A study of Homo sapiens and Mus musculus with 100 samples.

How the data were processed

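Messenger RNA was measured in HepG2 and Caco-2 cells, in AhR-flox mouse hepatocytes and in mouse liver, each with and without vitamin B2. Per the labels' protocols, libraries were made with a QuantSeq kit that primes at the poly(A) tail and reads the 3′ ends of transcripts. That protocol speaks of cultured cells, and whether it covers the liver samples is not given. The labels give the treatment only as control or vitamin B2 deficiency. The dose of Kyn, the names of the inhibitors, the floxed exon and the guide site are not given in the sources used here. The mouse hepatocytes carry a label of 4 weeks, as the livers do.

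The values in all 8 tables are TPM, deposited by the authors and written by HOMER per the file headers, with 1 transcript and its length for each gene symbol. STAR, HOMER and Bowtie2 and the builds hg38 and mm10 are named in the submitters' processing notes, with no role for each. The trimming settings and the aligner options are not given. TPM divides reads by transcript length, whereas a 3′ kit yields about as many reads from a short as from a long transcript, so levels can be compared between samples but not between genes. The human files list 28035 genes and the mouse files 24940, with 0 repeated symbols. The TPM of the listed genes sums to 359500 to 405213 per human library and 569555 to 581347 per mouse library, less than the full TPM scale; the entries that hold the rest are not used here. No library was rescaled in the main analysis. A few very abundant transcripts can therefore shift all others, so splits into higher and lower genes after quantile normalization stand beside many of the counts. Reads without a strand setting cannot be assigned between overlapping genes, and near-identical copies (metallothioneins, Mup genes, the UGT1A locus, SAA genes) can share reads.

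Depth was recovered from the values. Low TPM multiplied by length were whole multiples of 1 value per library in 100% of the values checked (within 0.1 of a whole number, genes of up to 3000 bases, up to 20 reads). Replicate pairs were then compared on those reads. The mean chi-square per gene was at least 1.99 in every pair, where sampling alone gives about 1, and at most 3.4% of values were identical, so no library was counted as a repeat of another. Replicate 3 of the controls with AhR inhibitor stood apart from the others of its group, with a chi-square per gene of 29.3 and 27.6 against 7.81 between the other pair.

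Samples were grouped by their labels into 32 groups. Columns were matched to samples by name. The liver columns give the diet but not the animal, so they carry no number of the labels, and the 8 columns stand for 10 labelled liver samples, 2 of which were not analysed here. The headers also carry dates and runs. All groups of the guide RNA, IDO/TDO inhibitor, Kyn and mouse hepatocyte tables shared a date or run within their table, while in the AhR inhibitor table the libraries with inhibitor came from another run than those without. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Each table was tested on its own, since tables were made separately.

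Each table was fitted with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8) on log2(TPM + 1), with a group-means model and eBayes with trend and robust settings. Genes needed a TPM of 1 or more in at least 3 libraries (5 in liver). This left 12488 genes in the time course, 11888 in Caco-2, 11916 with the AhR inhibitor, 11470 with the IDO/TDO inhibitor, 11893 with guide RNA, 11798 with Kyn, 12155 in mouse hepatocytes and 10574 in liver. Tests were two-sided, and p was adjusted by Benjamini-Hochberg within each of 26 contrasts, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. An interaction is the deprivation (or Kyn) effect with the inhibitor, guide or Ad-Cre minus that without it. A count test was foreseen for counts, but the tables hold TPM, so the plan for TPM was used.

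Gene lists, 33 in all, were fixed before the data were examined, as were the groups, tests and most of the other settings. The lists described were chosen after their values were seen. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, the adjusted p being over lists with at least 4 tested members within each contrast. The sets of genes that moved at day 12 (a log2 fold change of at least 1) were tested in other tables with limma's fry, whose p says whether a set moves on balance in 1 direction, adjusted over all sets and contrasts so tested. AHR, CYP1A1, CYP1A2, CYP1B1, AHRR, TIPARP and NQO1 were to be named wherever measured. CYP1A2, CYP1B1 and AHRR did not pass the filter in human cells, nor did Cyp1a1, Cyp1b1 and Ahrr in mouse. Also named were the 6 highest and 6 lowest fold changes past the threshold with a mean of at least 10 TPM and no overlap between groups (overlap allowed for interactions), and up to 4 members of each described list. Non-coding, antisense and pseudogene symbols were left out. Where that gave more than about 10 genes, some are left to the counts. Results for a few genes are not reported here.

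The procedure was tested on simulated reads with 66 or 67 genes changed per fold. For HepG2 day 12 it recovered 55.2% of genes changed 1.5-fold and 100% at 2-fold and 4-fold. It made 25 false calls among 11116 genes, more than the threshold alone would give. For Kyn it recovered 44.8, 97 and 98.5% with 12 false calls among 11236, and for liver 59.7, 100 and 100% with 12 among 10502. The data hold far more calls (6543 at day 12), so these rates may not hold there. Liver changes above 2-fold can be missed, such as Cyp2a4 (log2 fold change 2.221, limma adjusted p = 0.168). The other settings fixed then were quantile normalization, a pseudocount of 0.1, no filter on low values, limma without trend or robust settings, only the groups of a contrast, the replicate number as a block, leaving out each library, an estimated correlation for lists, and other thresholds or another day for the day 12 sets. Median scaling, scaling without the 10 highest genes, voom on the recovered reads, reads thinned to equal depth and a liver filter of 4 libraries were added after the values were seen. Coordinates are those in the files. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.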

Results

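Messenger RNA levels were collected for 100 samples in 32 groups, of which 98 columns in 8 tables were used. The groups compare cells or mice kept without vitamin B2 (riboflavin, the precursor of the flavin cofactors FMN and FAD) with controls. They ask how far the response depends on AhR, the aryl hydrocarbon receptor, a ligand-activated transcription factor. HepG2, a human liver tumour line that makes many hepatocyte proteins, was sampled at days 3, 6, 9 and 12. At day 12 it was also sampled with an AhR inhibitor, with an IDO/TDO inhibitor (directed at enzymes that open the tryptophan ring), with a control or an AhR guide RNA, and with a treatment labelled Kyn. Caco-2, a colon tumour line with enterocyte features, was sampled at day 9. Mouse material was AhR-flox hepatocytes given Ad-Cont or Ad-Cre, and whole liver. All groups held 3 libraries except the liver groups, which held 4 columns each. Reads recovered from the values (to the nearest 100 per library) numbered 4049600 to 5822600 in the Kyn table, 5213400 to 6518000 in Caco-2 and 6263500 to 7810000 in the mouse hepatocytes. They numbered 6067500 to 7671300 in the guide RNA table, 6827700 to 11040400 in the time course and 11958200 to 14258200 in the IDO/TDO inhibitor table. They numbered 5891600 to 19428000 in the AhR inhibitor table and 13915000 to 19644000 in liver. Values after ± are standard errors for log2 fold changes and SD for TPM, with n = 3 libraries per group unless stated, and each adjusted p is from limma over all genes of a table or from camera for a gene list; counts adjusted by list are over the members of that list alone.

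HepG2 cells without vitamin B2 carried more and larger differences from their controls at each later day. At day 12 SPP1, a secreted phosphoprotein (chromosome 4, 87975650 to 87983411), reached 955 ± 19.3 TPM against 9.31 ± 1.58, a log2 fold change of 6.55 ± 0.08 (adjusted p = 8.86e-25). HAMP, the iron hormone hepcidin, rose by 5.85 ± 0.14, AKR1B10, an aldo-keto reductase, by 4.37 ± 0.11, and MT2A, a metallothionein, by 4.23 ± 0.12. TIMP1, a metalloproteinase inhibitor, rose by 4.06 ± 0.10. PCK1, a rate-limiting enzyme of gluconeogenesis (chromosome 20, 57561081 to 57566457), fell by 4.12 ± 0.12, from 36.0 ± 2.42 to 1.12 ± 0.183 TPM. AFP, the fetal serum protein (−3.24 ± 0.06), the inositol transporter SLC5A3 (−2.73 ± 0.13) and the inhibitor heavy chain ITIH3 (−2.52 ± 0.10) fell. In controls SPP1 stood at 542 ± 13.8, 242 ± 8.98, 54.9 ± 6.19 and 9.31 ± 1.58 TPM at days 3, 6, 9 and 12, and in deprived cells at 792 ± 38.4, 731 ± 7.23, 858 ± 44.3 and 955 ± 19.3. PCK1 stood at 0.671 ± 0.0925 in day 3 controls and AFP at 863 ± 29.9, against 5359 ± 225 TPM for AFP at day 12, while in deprived cells AFP stood at 670.0 ± 13.3 and 566 ± 29.7. Differences between days were not themselves tested. The numbers of genes higher and lower were 342 and 250 at day 3, 2374 and 1746 at day 6, 3671 and 2463 at day 9, and 4247 and 2296 at day 12. The day 3 total of 592 was 351 to 404 on leaving out 1 library. The median over all genes at day 12 was 0.096. Quantile normalization gave 344 higher and 278 lower at day 3, 2094 and 1986 at day 6, 3132 and 3095 at day 9, and 3319 and 3097 at day 12. After the values were seen, median scaling was added and gave 2033 and 2040 at day 6, 3004 and 3172 at day 9, and 3200 and 3267 at day 12, and voom gave 363 and 458, 2064 and 2183, 2984 and 3106, and 3417 and 3399 at the 4 days. The 10 most abundant genes took 17.4 ± 0.36% of listed TPM in day 12 controls and 7.1 ± 0.08% in deprived cells.

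CYP1A1, the monooxygenase most used as a readout of AhR (chromosome 15, 74719542 to 74725610), did not pass the test at day 3 (log2 fold change −0.01 ± 0.12, adjusted p = 0.993). It rose by 1.16 ± 0.12 at day 6, 1.59 ± 0.12 at day 9 and 2.45 ± 0.12 at day 12, where it stood at 23.8 ± 0.707 against 3.57 ± 0.648 TPM (adjusted p = 1.48e-13). Controls stood at 5.49 ± 0.753, 2.40 ± 0.1 and 2.42 ± 0.347 TPM at days 3, 6 and 9, and deprived cells at 5.54 ± 1.37, 6.56 ± 0.244 and 9.26 ± 0.595. NQO1, a quinone reductase shared by AhR and NRF2, rose at every day, by 0.39 ± 0.06, 0.77 ± 0.06, 1.34 ± 0.06 and 1.73 ± 0.06. AHR itself (chromosome 7, 17298652 to 17346151) rose at days 6 and 9, by 0.36 ± 0.08 and 0.30 ± 0.08. At day 12 AHR stood at −0.19 ± 0.08 (adjusted p = 0.0459), a call lost without any 1 of the 6 libraries (adjusted p = 0.0515 to 0.188). TIPARP, another AhR target, stood at 0.08 ± 0.07, 0.20 ± 0.07, 0.10 ± 0.07 and 0.03 ± 0.07. Its only call, at day 6 (adjusted p = 0.0459), was lost after quantile normalization (adjusted p = 0.107) and without any 1 library but deprived replicate 3 (adjusted p = 0.0723 to 0.164). Of 7 AhR targets measured, 2 rose at day 3, 6 at days 6 and 9, and 5 at day 12, none fell, and the counts were equal when adjusted by list. UGT1A6, a glucuronidation enzyme, rose by 1.42 ± 0.12 and SLC7A5, an amino acid transporter, by 0.76 ± 0.07 at day 12. The list lay above other genes at each day (adjusted p = 0.00285, 0.000182, 8.9e-05 and 0.000866), also with an estimated correlation.

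**Figure D1:**
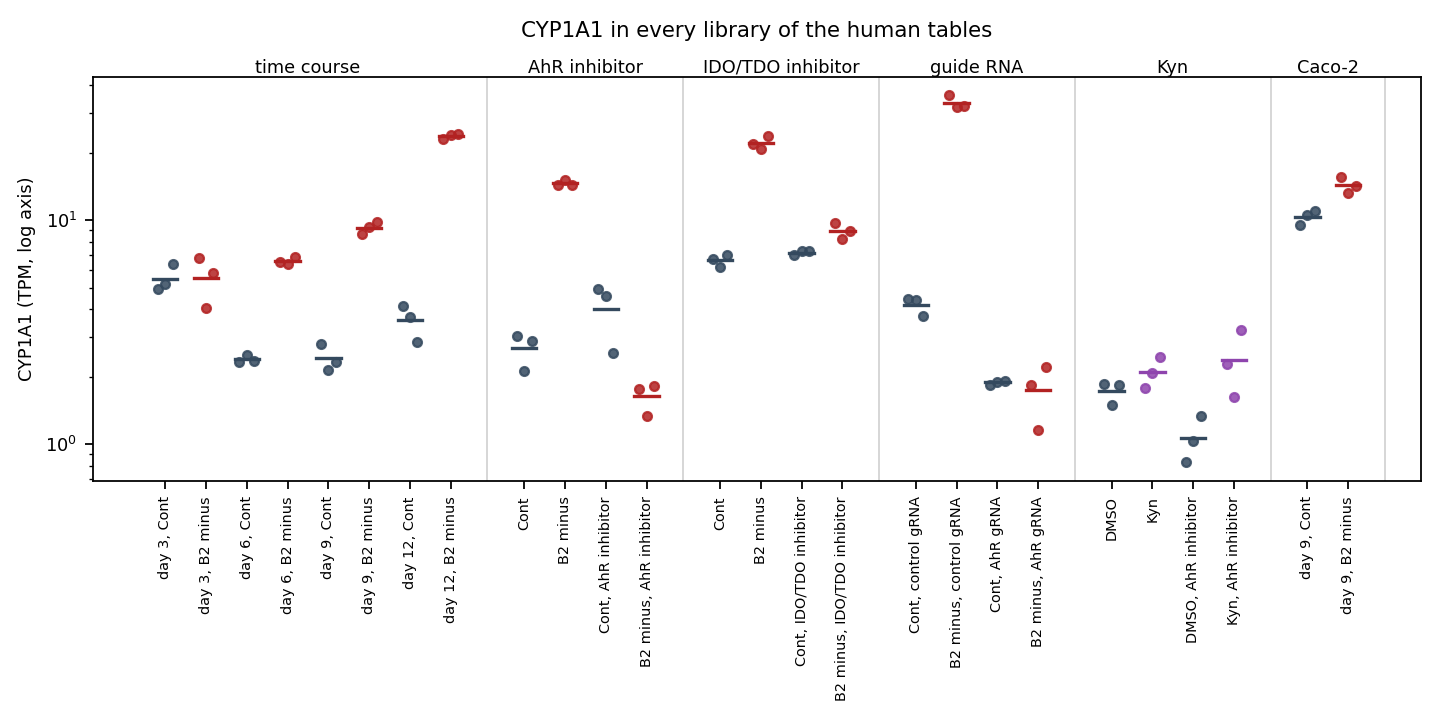
CYP1A1 level in TPM (vertical log axis) in every library of the human tables; points are libraries, bars are group means, red marks B2-deprived groups, purple Kyn and dark blue the controls, and tables were normalized separately, so levels are compared only within a block. In the guide RNA block the deprived cells average 33.5 TPM with the control guide and 1.74 TPM with the AhR guide.

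Antioxidant and stress genes rose early. Of 18 NRF2 targets, 13 rose at day 3, 17 at day 6, 16 at day 9 and 16 at day 12, where 1 fell (0 without control or deprived replicate 2); adjusted by list the rises were 15, 17, 16 and 16. The list stood above other genes at each day (adjusted p = 8.61e-23, 5.3e-16, 1.37e-11 and 2.39e-10). AKR1B10 rose by 1.79 ± 0.11 at day 3 and 4.63 ± 0.11 at day 9. At day 12 MGST1, a membrane glutathione transferase, rose by 2.35 ± 0.05, the ferritin light chain FTL by 2.28 ± 0.06 and HMOX1, which degrades haem, by 2.16 ± 0.08. Of 23 genes of the integrated stress response, 17 rose at day 3 and 22 at day 6 (21 and 22 adjusted by list), then 19 at day 9 (19 adjusted by list). ASNS, which makes asparagine, rose by 1.02 ± 0.08 at day 3 and 1.89 ± 0.08 at day 6. The cytokine GDF15 rose by 2.10 ± 0.07 at day 12, when 13 members rose, 4 fell (13 and 4 adjusted by list) and the list did not pass (adjusted p = 0.0661). Of 14 p53 targets, 4, 11, 12 and 12 rose at the 4 days (as many adjusted by list), and 0, 1, 1 and 1 fell. CDKN1A, which stops the cell cycle, rose by 1.28 ± 0.05 at day 6 and 1.62 ± 0.05 at day 12. The p53 list passed at each day (adjusted p = 3.89e-06, 5.67e-06, 5.82e-06 and 0.000207), also with an estimated correlation, as did the other lists named here where they passed.

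Lipid synthesis and protein folding genes fell. Of 24 genes of cholesterol synthesis, none rose and 13 fell at day 3, 23 at day 6, 22 at day 9 and 22 at day 12 (17, 23, 23 and 22 adjusted by list); 1 rose at day 9 without deprived replicate 3. At day 9 FDPS, which makes farnesyl diphosphate (−2.37 ± 0.10), and HMGCS1, which makes the HMG-CoA of the pathway (−1.89 ± 0.06), fell. The list median was −1.29 at day 9 and −0.88 at day 12 relative to all genes (adjusted p = 8.39e-24 and 4.6e-18). Of 19 genes of fatty acid and triglyceride synthesis, 3, 11, 13 and 13 fell, and 0, 1, 2 and 3 rose (5, 11, 13 and 13 fell adjusted by list). The 3 at day 3 were 1 without control replicate 1 or 3 or deprived replicate 1 or 2, and the 2 that rose at day 9 were 1 without any 1 library but deprived replicate 1. The desaturases FADS2 and SCD stood at −2.03 ± 0.07 and −1.69 ± 0.05 at day 9, and the elongase ELOVL6 at −1.96 ± 0.09 at day 12. This list passed at each day, but at day 3 not with an estimated correlation (adjusted p = 0.115). Of 15 chaperones of the endoplasmic reticulum, 13 fell at days 3 and 6, 9 at day 9 and 7 at day 12, when 5 rose (8 fell and 5 rose adjusted by list). HSPA5, the main chaperone of that compartment, stood at −0.73 ± 0.07 at day 3 and −1.04 ± 0.07 at day 6. At day 12 the list passed (adjusted p = 0.0399), but not with an estimated correlation (adjusted p = 0.187). FABP1, the liver fatty acid binding protein, stood at 466 ± 65.1 against 2130.0 ± 135 TPM in controls at day 6 (adjusted p = 1.02e-15), and fell by 2.92 ± 0.07 at day 9.

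Several groups moved at different times. Of 14 hypoxia genes 5 rose at day 3, including VEGFA by 0.47 ± 0.07, then 8 fell and 1 rose at day 6, and 14 fell at day 9 and 8 at day 12 (8 rose at day 3, and 8, 14 and 8 fell, adjusted by list). The 5 at day 3 were 3 without control or deprived replicate 1, and the 8 at day 12 were 5 without control replicate 2. CA9, a carbonic anhydrase, stood at −3.06 ± 0.19 and NDRG1 at −1.81 ± 0.15 at day 9 (list adjusted p = 1.52e-11). At days 6 and 12 the list did not pass with an estimated correlation (adjusted p = 0.154 and 0.157). Of 18 secreted hepatocyte proteins, 4, 9, 12 and 11 fell and 0, 3, 4 and 6 rose (8, 10, 12 and 11 fell adjusted by list), the 4 at day 3 being 2 without any 1 library but deprived replicate 1. At day 12 ALB, albumin, fell by 2.32 ± 0.05 and transferrin, TF, fell by 2.37 ± 0.05, whereas haptoglobin, HP, rose by 2.33 ± 0.13 and hemopexin, HPX, by 3.06 ± 0.20. That list passed at each day, but at days 6 and 12 not with an estimated correlation (adjusted p = 0.154 and 0.111). Of 9 bile acid genes, 8 fell and 1 rose at day 12 (as many adjusted by list; 0 rose without control or deprived replicate 2 or 3), among them the conjugating enzyme BAAT at −1.81 ± 0.16 (list adjusted p = 8.01e-05). Of 20 cell cycle genes, 15 fell at day 6 and 12 at day 9, when 2 rose, and 15 rose at day 12 (17, 13 and 16 adjusted by list). TOP2A, a topoisomerase of dividing cells, fell by 0.88 ± 0.08 at day 9, and PCNA and RRM2, of DNA synthesis, rose by 1.58 ± 0.05 and 1.48 ± 0.10 at day 12. The day 9 and day 12 calls of that list were lost with an estimated correlation (adjusted p = 0.103 and 0.119). Of 39 nuclear genes of the respiratory chain, 27 rose and 2 fell at day 9 (1 fell without control replicate 3), and 33 rose at day 12 (27 and 34 adjusted by list). COX8A rose by 1.14 ± 0.05 at day 12 (list adjusted p = 6.92e-08).

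**Figure D2:**
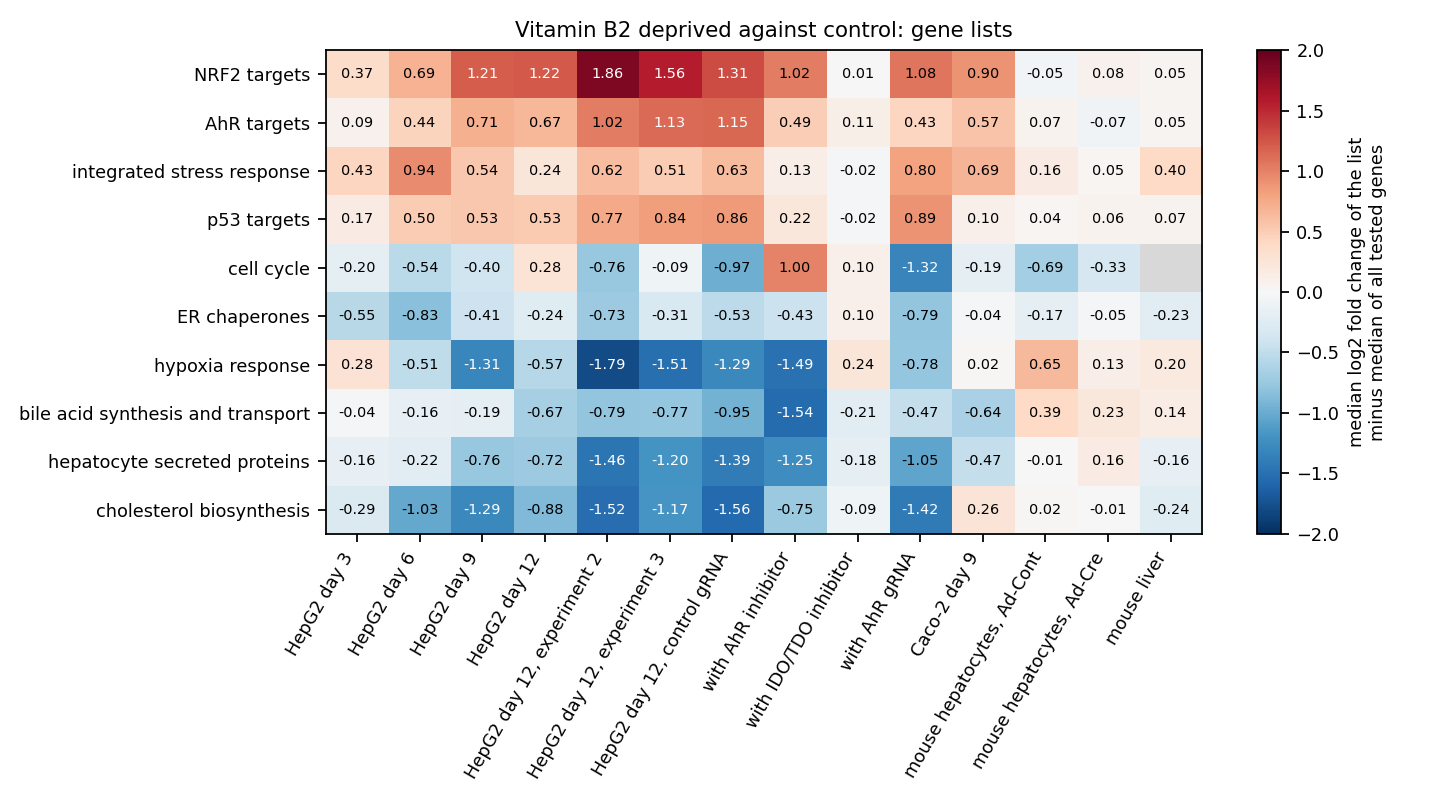
Median log2 fold change (TPM + 1) of 10 gene lists, given as rows, in 14 comparisons of vitamin B2 deprivation with control, given as columns, after subtracting the median of all tested genes; red is higher, blue lower and grey fewer than 4 tested genes, each table was normalized separately, and the cells carry no test. Cholesterol synthesis lies at −1.29 in HepG2 and 0.26 in Caco-2 at day 9.

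In Caco-2 cells deprived for 9 days CXCL1 and CCL20, both chemokines, rose by 2.47 ± 0.19 and 2.27 ± 0.20, and CYR61, a matrix protein and YAP target, by 2.34 ± 0.10. ATF3, a stress transcription factor, rose by 2.33 ± 0.13, the phosphatase DUSP1 by 2.31 ± 0.17 and ANKRD1, another YAP target, by 2.00 ± 0.06. The sulfate transporter SLC26A2 (−1.93 ± 0.13), creatine kinase CKB (−1.88 ± 0.07), the secreted protein MSMB (−1.67 ± 0.08) and APOB, the apolipoprotein of chylomicrons (−1.43 ± 0.12) fell. CYP1A1 rose by 0.43 ± 0.10 (14.3 ± 1.2 against 10.4 ± 0.745 TPM, adjusted p = 0.00623), TIPARP by 1.03 ± 0.15 and NQO1 by 0.42 ± 0.10. AHR did not pass (0.18 ± 0.09, adjusted p = 0.159). In all, 1695 genes were higher and 2316 lower (2000 and 1924 quantile-normalized, and 2403 and 2251 with voom).

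By list, 7 of 9 AhR targets rose in Caco-2 (7 adjusted by list), with EREG, an EGF receptor ligand, at 1.25 ± 0.09 and UGT1A6 at 1.31 ± 0.09. Of 18 NRF2 targets 12 rose and 2 fell (as many adjusted by list; 1 fell without deprived replicate 1 or 2), with OSGIN1, an oxidative stress response gene, at 1.88 ± 0.10. Of 24 integrated stress response genes 15 rose (17 adjusted by list), with GDF15 at 1.79 ± 0.05. Cholesterol synthesis went the other way from HepG2: 13 of 25 genes rose and 4 fell (13 and 6 adjusted by list; 2 fell without control replicate 1), with INSIG1, a sterol sensor, at 0.78 ± 0.05 and the reductase TM7SF2 at −1.15 ± 0.09; the difference between lines was not tested. Of 12 acyl-CoA dehydrogenases and electron transfer flavoproteins, which hold FAD, 8 fell (9 adjusted by list; 5 without deprived replicate 3), including ACADM at −0.84 ± 0.11. Of 39 respiratory chain genes 23 fell (24 adjusted by list; 15 without deprived replicate 3), including NDUFA8 at −0.54 ± 0.07. Of 9 enterocyte markers 6 fell and 1 rose (as many adjusted by list), with MTTP, which loads lipoproteins, at −1.37 ± 0.12. These 7 lists passed camera, and none held with an estimated correlation (adjusted p = 0.0931, 0.088, 0.0931, 0.0931, 0.0931, 0.111 and 0.121 in that order).

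A further HepG2 set at day 12 crossed deprivation with an AhR inhibitor. Per the file headers, the libraries with inhibitor came from another run and date than those without it, so the inhibitor effect and the interaction cannot be told apart from the run, whereas each deprivation effect lies within 1 run. Without inhibitor AKR1B10 rose by 6.37 ± 0.12, SPP1 by 5.80 ± 0.08, HAMP by 5.42 ± 0.15, S100A11, a calcium-binding protein, by 5.16 ± 0.25 and TIMP1 by 5.12 ± 0.09. PCK1 (−4.54 ± 0.12), FABP1 (−4.06 ± 0.06), AFP (−3.87 ± 0.06), CCL20 (−3.70 ± 0.09) and FAM13A (−3.69 ± 0.40) fell. With inhibitor SPP1 and HAMP rose by 6.21 ± 0.08 and 6.21 ± 0.15, TIMP1 by 4.72 ± 0.09, S100A11 by 4.58 ± 0.25 and the keratin KRT19 by 4.34 ± 0.20. PCK1 (−4.95 ± 0.12), the troponin TNNI2 (−4.41 ± 0.42), G6PC, which releases glucose (−4.16 ± 0.16), the ion transport regulator FXYD1 (−3.88 ± 0.21) and CP, ceruloplasmin (−3.80 ± 0.14) fell. Genes higher and lower numbered 5316 and 2015 without inhibitor (3440 and 3183 quantile-normalized). With it they numbered 5375 and 1482 (3170 and 2734 quantile-normalized). All-gene medians were 0.226 and 0.243.

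CYP1A1 rose by 2.09 ± 0.17 without the inhibitor, to 14.6 ± 0.513 TPM from 2.68 ± 0.496, and fell by 0.90 ± 0.17 with it, to 1.63 ± 0.266 from 4.01 ± 1.29. Their difference was −2.99 ± 0.24 (adjusted p = 2.78e-06), and NQO1 differed by −0.24 ± 0.09 (adjusted p = 0.0745; 0.03 without inhibitor control replicate 3). TIPARP did not pass in either medium contrast (adjusted p = 0.357 and 0.408). AHR rose by 0.95 ± 0.21 without inhibitor, and with inhibitor stood at 0.30 ± 0.21 (adjusted p = 0.239, and 6.63e-05 without inhibitor control replicate 3). In control medium the inhibitor libraries held more TSC22D3, a glucocorticoid-induced leucine zipper protein (2.46 ± 0.35) and FBLN5 (2.00 ± 0.14). They held less FKBP2 (−1.84 ± 0.12) and TOP2A (−1.67 ± 0.12). CYP1A1 stood there at 0.42 ± 0.17 (adjusted p = 0.0706, and 0.00093 without inhibitor control replicate 3). In that contrast 1742 genes were higher and 2536 lower (2221 and 2335 quantile-normalized, and 2220 and 2106 with voom). The interaction held 1536 above 0 and 1140 below (1527 and 1456 quantile-normalized, and 1428 and 1489 with voom).

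Of 7 AhR targets 6 rose without the inhibitor, 4 rose and 1 fell with it, and 3 differed downward (6, 4, 1 and 4 adjusted by list). That list passed without inhibitor and in the interaction, but not with an estimated correlation (adjusted p = 0.105 and 0.255). In control medium 3 of that list were higher with inhibitor (5 without inhibitor control replicate 3) and 1 lower (5 and 1 adjusted by list). Of 18 NRF2 targets 17 rose without and 17 with the inhibitor (17 each adjusted by list), and 13 differed downward between them (13 adjusted by list), AKR1B10 by −2.63 ± 0.16 and SRXN1, a sulfiredoxin, by −1.68 ± 0.19; in control medium 12 were higher and 1 lower with inhibitor (as many adjusted by list). Of 24 cholesterol genes 23 fell without the inhibitor, 16 fell and 1 rose with it (23, 16 and 2 adjusted by list), and 20 differed upward and 1 downward (21 and 1 adjusted by list), FDFT1, the squalene synthase, by 1.34 ± 0.10; in control medium 8 were higher (13 without inhibitor control replicate 3) and 3 lower with inhibitor (9 and 4 adjusted by list). The 1 that rose with inhibitor was 2 without inhibitor control replicate 1 and 0 without inhibitor control replicate 2 or any 1 deprived inhibitor replicate, and 0 differed downward without deprived replicate 2 or 3 or deprived inhibitor replicate 3. Without inhibitor 1 rose when deprived replicate 1 was left out. Of 14 hypoxia genes 14 fell without and 13 with it (14 each adjusted by list), CA9 at −3.42 ± 0.20 and −4.17 ± 0.20, and none passed the interaction (0 adjusted by list). Without inhibitor control replicate 1, 2 or 3, 2, 1 and 1 differed upward, and 3 differed downward without the last of these and 1 without control replicate 3 or deprived replicate 1. Of 18 secreted proteins 15 and 12 fell and 3 rose in each (as many adjusted by list), TF at −2.96 ± 0.09 and −2.98 ± 0.09. Of 20 cell cycle genes 14 fell and 1 rose without the inhibitor, while 20 rose with it, RRM2 by 2.51 ± 0.13 and PCNA by 1.83 ± 0.10 (14 and 20 adjusted by list). Of the 20 genes, 19 differed upward in the interaction and 18 were lower with inhibitor in control medium (20 and 18 adjusted by list). With an estimated correlation the NRF2, cholesterol and secreted lists held without inhibitor (adjusted p = 0.0306, 0.0353 and 0.0306), and the secreted list held with it (0.0351). With that correlation the NRF2, cholesterol, hypoxia and cell cycle calls with inhibitor were lost (adjusted p = 0.0526, 0.0888, 0.13 and 0.143), as were hypoxia and cell cycle without it (adjusted p = 0.133 and 0.148). Also lost were the NRF2, cholesterol and cell cycle calls of the interaction (adjusted p = 0.07, 0.138 and 0.0753) and the cell cycle call in control medium (adjusted p = 0.199).

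Another set crossed deprivation with an IDO/TDO inhibitor, all 12 libraries sharing 1 date and folder in the headers. Without inhibitor SPP1 rose by 6.93 ± 0.11, AKR1B10 by 5.14 ± 0.14, AREG, an EGF receptor ligand, by 4.43 ± 0.11, S100A11 by 4.27 ± 0.22 and HAMP by 4.24 ± 0.22. PCK1 (−4.94 ± 0.09), INHA, an inhibin subunit (−4.42 ± 0.17), ARG1, an enzyme of the urea cycle (−4.03 ± 0.09) and FBLN5 (−3.57 ± 0.13) fell. With inhibitor these differences were small: SPP1 stood at 5.69 ± 0.8 TPM in deprived and 3.88 ± 0.443 in control medium, against 540 ± 20.6 and 3.46 ± 0.597 without it. PCK1 stood at 82.7 ± 9.88 and 79.3 ± 3.71 TPM with inhibitor. The interaction was −6.48 ± 0.15 for SPP1, −5.15 ± 0.20 for AKR1B10 and 4.99 ± 0.12 for PCK1 (adjusted p = 3.84e-14, 1.12e-10 and 6.61e-14). CYP1A1 rose by 1.60 ± 0.08 without inhibitor, stood at 0.29 ± 0.08 with it (adjusted p = 0.121) and differed by −1.31 ± 0.12 (adjusted p = 1.96e-07). NQO1 differed by −2.47 ± 0.12 and AHR, which rose by 0.69 ± 0.11 without inhibitor, by −0.53 ± 0.16 (adjusted p = 0.156 quantile-normalized).

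Without the IDO/TDO inhibitor 6147 genes were higher and 1644 lower (3507 and 3125 quantile-normalized; all-gene median 0.296). With it 98 were higher and 61 lower (75 and 72 quantile-normalized). The total of 159 with inhibitor was 72, 64 or 60 without inhibitor control replicate 1, 2 or 3, and 97 or 65 without deprived inhibitor replicate 1 or 2. The interaction held 1400 genes above 0 and 4756 below (2512 and 2678 quantile-normalized; median −0.271). Among genes past the test with inhibitor, TUBB2B, a tubulin, rose by 0.69 ± 0.09, FILIP1L by 0.66 ± 0.09 and ID1, a BMP target, by 0.61 ± 0.07. MT1E, a metallothionein whose reads a near-identical copy can share (−1.49 ± 0.17) and the trypsin inhibitor SPINK1 (−0.87 ± 0.08) fell. In control medium the inhibitor changed 1 gene, GTPBP2, a GTP-binding protein named after its values were seen, which stood at 5.92 ± 0.0975 against 3.18 ± 0.36 TPM (log2 fold change 0.73 ± 0.09, adjusted p = 0.00698). That count was 0 without control replicate 3 or without inhibitor control replicate 1, 2 or 3.

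Of 6 AhR targets 5 rose without the IDO/TDO inhibitor, 1 rose with it and 5 differed downward (5, 2 and 5 adjusted by list). The 1 with inhibitor was 0 without inhibitor control replicate 1 or 2, and 1 differed upward without control replicate 1. That list passed without inhibitor and in the interaction, but not with an estimated correlation (adjusted p = 0.24 and 0.259). Of 18 NRF2 targets, 17 rose without inhibitor, none rose and 1 fell with it, and 15 differed downward (17, 2 fallen and 15 adjusted by list); MGST1 rose by 2.87 ± 0.07 and differed by −2.82 ± 0.10. The 1 that fell was 0 without any 1 library but deprived inhibitor replicate 1. Of 24 cholesterol genes 22 fell and 1 rose, none passed with inhibitor, and 22 differed upward and 1 downward (as many adjusted by list), FDPS by −2.05 ± 0.06 and 1.98 ± 0.08; 0 rose without control replicate 1 or 3 or deprived replicate 1 or 2. Of 14 hypoxia genes 14 fell, 2 rose with inhibitor, BNIP3 among them by 0.39 ± 0.06, and 14 differed upward (14, 11 and 14 adjusted by list). The 2 with inhibitor were 5 without deprived inhibitor replicate 3 and 1 without any other 1 library. Of 22 integrated stress response genes 21 rose and 19 differed downward (21 and 19 adjusted by list); NUPR1, a stress-induced chromatin protein, rose by 2.91 ± 0.10 without inhibitor and fell by 0.81 ± 0.10 with it. Of 18 secreted proteins 12 fell and 5 rose without inhibitor, 4 fell with it, and 11 differed upward and 5 downward (12 and 5, 7, and 12 and 5 adjusted by list); VTN, vitronectin, fell by 0.36 ± 0.06 with it. The 4 with inhibitor were 2 without any 1 library but deprived inhibitor replicate 3, and 2 after quantile normalization. The other 5 lists held with an estimated correlation without inhibitor (adjusted p = 0.0311, 0.0312, 0.0278, 0.0292 and 0.0222) and in the interaction (0.0266, 0.0436, 0.0266, 0.0266 and 0.0266). With inhibitor the secreted list held (adjusted p = 0.0195), while the cholesterol and hypoxia calls were lost (adjusted p = 0.471 and 0.115).

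In the guide RNA set AHR was measured first, as the targeted gene. With the control guide it stood at 4.54, 4.37 and 6.51 TPM in control medium and 8.26, 6.09 and 6.07 TPM in deprived medium. With the AhR guide it stood at 4.48, 4.76 and 4.88 TPM in control and 7.94, 8.09 and 7.06 TPM in deprived medium. The AhR guide left AHR at −0.09 ± 0.13 in control medium (adjusted p = 0.641). The guide's site is not given and the tags come from transcript ends, so the AHR level does not check the edit. CYP1A1 stood at 4.2 ± 0.39 TPM with the control guide and 1.88 ± 0.0426 with the AhR guide in control medium (log2 fold change −0.85 ± 0.12, adjusted p = 0.000129). With the control guide deprivation took it to 33.5 ± 2.33 TPM, up by 2.73 ± 0.12 (adjusted p = 4.88e-10). With the AhR guide it stood at 1.74 ± 0.537 TPM (−0.10 ± 0.12, adjusted p = 0.535), and the interaction was −2.83 ± 0.17 (adjusted p = 1.08e-06). NQO1 rose by 1.49 ± 0.08 and 0.75 ± 0.08 and differed by −0.74 ± 0.12. AHR rose by 0.35 ± 0.13 with the control guide, a call lost after quantile normalization (adjusted p = 0.292) and without control replicate 1 or 2 or deprived replicate 1 (adjusted p = 0.115, 0.131 and 0.163), and by 0.60 ± 0.13 with the AhR guide.

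With the control guide SPP1 rose by 5.00 ± 0.10, HAMP by 4.53 ± 0.17, AREG by 4.40 ± 0.18, TIMP1 by 3.88 ± 0.16 and S100A11 by 3.72 ± 0.12. PCK1 (−4.39 ± 0.16), FABP1 (−3.77 ± 0.08), CCL20 (−3.31 ± 0.07) and AFP (−3.20 ± 0.06) fell. With the AhR guide PHLDA2, an imprinted growth gene, rose by 3.69 ± 0.08, TIMP1 by 3.59 ± 0.16, SPP1 by 3.57 ± 0.10 and HAMP by 3.39 ± 0.17. MT1M (−3.83 ± 0.28), FABP1 (−3.36 ± 0.08), FADS2 (−2.45 ± 0.08) and AFP (−2.42 ± 0.06) fell. In control medium the AhR guide raised the metallothioneins MT1M (4.70 ± 0.28) and MT1G (3.89 ± 0.27), near-identical copies that can share reads, and HPX (3.03 ± 0.18). There it lowered G6PC (−3.08 ± 0.15), IGFBP1, an insulin-repressed secreted protein (−2.36 ± 0.11), SLC5A3 (−2.28 ± 0.16) and PCK1 (−2.03 ± 0.16). Interactions were 2.35 ± 0.23 for SLC5A3, 1.90 ± 0.23 for PCK1, −3.33 ± 0.40 for MT1M and −2.21 ± 0.11 for MT2A. Genes higher and lower numbered 5183 and 2033 with the control guide (3387 and 3103 quantile-normalized) and 4476 and 1855 with the AhR guide (2996 and 2828). They numbered 2775 and 1590 for the guide in control medium (2042 and 2143 quantile-normalized), and 733 above and 979 below 0 in the interaction (897 and 716).

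Of 6 AhR targets 5 rose with the control guide, 4 rose with the AhR guide and 3 differed downward (5, 4 and 5 adjusted by list); 5 differed downward without control replicate 3 of the control guide. That list passed with the control guide and in the interaction, but not with an estimated correlation (adjusted p = 0.0601 and 0.0663). Of 24 cholesterol genes 23 fell with the control guide and 22 with the AhR guide, 1 rose in each, and 6 differed upward and 1 downward (23, 22, 1, 9 and 1 adjusted by list), DHCR7 by 0.52 ± 0.10. With the AhR guide 0 rose without its control replicate 2 or deprived replicate 1, and 0 differed downward without any 1 library but control replicate 2 or deprived replicate 1 of the control guide or deprived replicate 1 of the AhR guide. Of 18 NRF2 targets 14 and 16 rose, 1 fell with the control guide, and 7 differed downward and 2 upward (15, 16, 1, 8 and 3 adjusted by list), with FTL at −0.81 ± 0.09. With the control guide 2 fell without control replicate 3. The 2 that differed upward were 1 without control replicate 1 or 2 or deprived replicate 2 or 3 of the control guide, or control replicate 1 or 3 or deprived replicate 1 of the AhR guide. Of 18 secreted proteins 13 and 13 fell, 3 and 2 rose, and 5 differed upward and 3 downward (14, 13, 3, 2, 5 and 3 adjusted by list), with ALB at 0.94 ± 0.08. Of 14 hypoxia genes 14 and 9 fell, 2 rose with the AhR guide, 7 differed upward and 13 were lower with the AhR guide in control medium (14, 9, 2, 8 and 13 adjusted by list), with EGLN3, an oxygen-sensing hydroxylase, at −2.64 ± 0.15 with the control guide; the 2 that rose were 1 without control replicate 2 or 3 or deprived replicate 2. Of 20 cell cycle genes 15 and 18 fell and 1 rose with the control guide, TOP2A at −1.92 ± 0.09 and −1.81 ± 0.09, and 19 were higher with the AhR guide in control medium (15, 19 and 19 adjusted by list). In control medium 3, 11, 9 and 4 of the AhR, cholesterol, NRF2 and secreted lists were higher and 2, 3, 5 and 6 lower with the AhR guide (as many adjusted by list). With an estimated correlation the cholesterol, NRF2 and secreted lists held with either guide, and hypoxia held with the control guide (adjusted p = 0.0439). Hypoxia with the AhR guide was lost (adjusted p = 0.142), as was the cell cycle with either guide (adjusted p = 0.0891 and 0.0548). Both were lost in control medium (adjusted p = 0.15 and 0.15). So were the cholesterol, NRF2, secreted and hypoxia calls of the interaction (adjusted p = 0.274, 0.0871, 0.116 and 0.118).

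Across the 4 HepG2 day 12 comparisons without inhibitor or AhR guide, which share no library, deprivation effects correlated across genes at Pearson 0.744 to 0.868, genes not being independent replicates. Of genes called in both of a pair, 94.2 to 98.8% moved the same way. Of 11087 genes tested in all 4, 2875 were higher and 881 lower throughout (450 and 9 if independent). Unscaled, 64.9 to 78.9% of called genes were higher (51.7 to 52.9% quantile-normalized), so a shared shift may add to this. Followed next were sets of 436 genes higher and 268 lower by a log2 fold change of at least 1 at time course day 12. Their medians were 1.40 and −1.36 in the AhR inhibitor set without inhibitor and 1.15 and −1.21 with it, and −0.28 and 0.04 in that interaction, which is confounded with the run (limma fry, adjusted p = 0.000755 and adjusted p = 0.235). With sets drawn at a log2 fold change of 0.58 the call of the higher set was lost there (−0.073) and the lower set gained one (0.086), as it did with sets drawn at day 9 (0.416). They were 1.31 and −1.28 with the control guide, 0.97 and −0.70 with the AhR guide, and −0.37 and 0.56 in that interaction (limma fry, adjusted p = 9.14e-07 and adjusted p = 1.07e-07). In control medium the AhR guide itself moved them as deprivation did, to 0.25 and −0.48 (limma fry, adjusted p = 5.85e-07 and adjusted p = 6.43e-08), which enters that interaction; the inhibitors left them there at −0.02 and 0.13 (AhR; adjusted p = 0.322 and adjusted p = 0.0014) and 0.00 and 0.02 (IDO/TDO; adjusted p = 0.867 and adjusted p = 0.635). They were 1.49 and −1.33 without the IDO/TDO inhibitor, 0.05 and −0.01 with it (adjusted p = 0.00132 and adjusted p = 0.602), and −1.43 and 1.31 in the interaction (limma fry, adjusted p = 1.04e-12 and adjusted p = 3.27e-10). In Caco-2 they were 0.15 and −0.27, the higher set turning to −0.04 with sets drawn at 0.58.

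**Figure D3:**
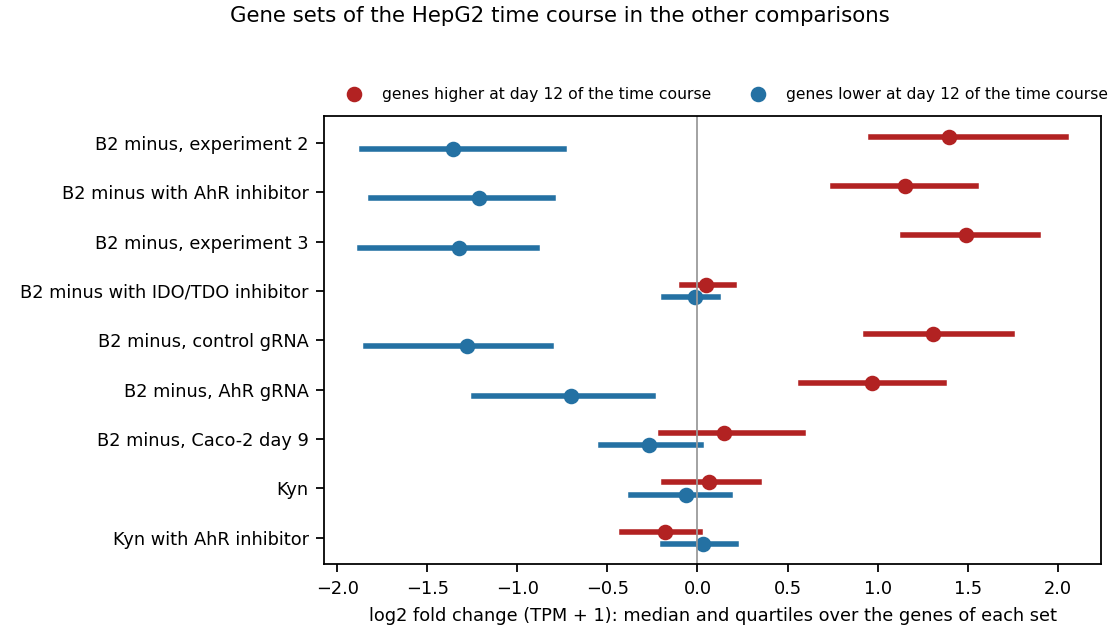
Log2 fold change (TPM + 1, horizontal axis) in 9 comparisons of the genes that were higher (red) or lower (blue) at day 12 of the HepG2 time course; points are medians over the genes of each set, bars run from the lower to the upper quartile, and tables were normalized separately. Medians with the IDO/TDO inhibitor are 0.05 and −0.01, against 1.49 and −1.33 without it.

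Kyn was compared with DMSO in HepG2 at day 12, with and without an AhR inhibitor, all in 1 run. Kyn raised the UGT1A glucuronidation genes, which share their last exons and count as 1 locus: UGT1A1 (chromosome 2, 233760273 to 233773299) went from 3.6 ± 0.932 to 38.0 ± 2.29 TPM, up by 3.10 ± 0.13 (adjusted p = 1.38e-09). With the inhibitor UGT1A1 stood at 4.8 ± 0.561 against 3.96 ± 0.3 TPM, an interaction of −2.88 ± 0.18 (adjusted p = 2.9e-07). Kyn lowered SAA4 (−2.46 ± 0.20), which shares reads with SAA2-SAA4, the homeobox factor IRX3 (−1.75 ± 0.10), FXYD2, a sodium pump subunit (−1.65 ± 0.11) and TNNI2 (−1.19 ± 0.14). The interaction was 2.56 ± 0.29 for SAA4. FXYD2, at 30.9 ± 4.42 TPM in DMSO and 9.14 ± 0.668 with Kyn, stood at 31.3 ± 2.96 and 28.1 ± 2.73 with inhibitor (interaction adjusted p = 5.06e-05). CYP1A1 did not pass with Kyn alone (0.18 ± 0.17, 2.11 ± 0.345 against 1.73 ± 0.198 TPM, adjusted p = 0.521). With inhibitor it rose by 0.69 ± 0.17, a call lost without DMSO inhibitor replicate 1 or 2 or Kyn inhibitor replicate 3 (adjusted p = 0.0719, 0.0516 and 0.0731), and the interaction did not pass (0.51 ± 0.24, adjusted p = 0.202). NQO1 stood at −0.07 ± 0.07 with Kyn alone, fell by 0.57 ± 0.07 with inhibitor and differed by −0.51 ± 0.10; AHR and TIPARP passed in none of these contrasts. Of 6 AhR targets 1, UGT1A6 of that locus, rose and 1 fell with Kyn, 1 rose and 3 fell with inhibitor, and 2 differed downward (1, 1, 1, 3 and 3 adjusted by list), and the list passed in none (adjusted p = 0.795, 0.794 and 0.218). With inhibitor Kyn raised the glutathione transferase GSTA1 by 1.65 ± 0.13 and lowered SPINK1 (−1.51 ± 0.16) and SPP1 (−1.20 ± 0.06).

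Kyn alone gave 721 genes higher and 654 lower (643 and 763 quantile-normalized, 654 and 725 with median scaling, and 822 and 1070 with voom), 915 in total without Kyn replicate 1. With inhibitor 205 were higher and 1074 lower (323 and 425 quantile-normalized, all-gene median −0.095), 1279 in total (751 to 997 without 1 library). The interaction held 249 above 0 and 806 below (372 and 364 quantile-normalized; median −0.121). In DMSO the inhibitor itself changed 0 genes by limma, with 520 at an unadjusted p under 0.05; voom on recovered reads also called 0, and 1 was called without DMSO inhibitor replicate 2. Of 18 secreted proteins 8 rose and 3 fell with Kyn (10 and 4 adjusted by list), with the fibrinogen chains FGA and FGG up by 1.49 ± 0.05 and 1.33 ± 0.04. With inhibitor 11 rose and none fell (11 and 1 adjusted by list), TTR, transthyretin, by 0.55 ± 0.05. After quantile normalization 8 rose and 1 fell, ALB turning from 0.47 to −0.379, and 1 fell without Kyn inhibitor replicate 1. Of 23 integrated stress response genes 9 fell with Kyn and 12 with inhibitor (10 and 13 adjusted by list), the transcription factor CEBPB at −0.45 ± 0.07 and −0.55 ± 0.07; with inhibitor 7 fell after quantile normalization. PLIN2, a lipid droplet coat protein among 10 PPARA targets, fell by 1.09 ± 0.07 with Kyn and differed by 1.25 ± 0.10; 4 of that list rose with inhibitor (5 adjusted by list; 2 without DMSO inhibitor replicate 2), FABP1 by 0.33 ± 0.03, at 0.00 after quantile normalization. Of 24 cholesterol genes 8 rose and 1 fell with inhibitor (14 and 2 adjusted by list), DHCR7, the last reductase of the pathway, by 0.35 ± 0.06. After quantile normalization 15 rose and 0 fell, and 5 rose without DMSO inhibitor replicate 1 or 3 or Kyn inhibitor replicate 2. The 1 that fell was 2 without DMSO inhibitor replicate 3 and 0 without DMSO inhibitor replicate 1 or Kyn inhibitor replicate 1 or 3. These lists held with an estimated correlation for Kyn (secreted 0.0187 and stress 0.0187). They held with inhibitor as well (adjusted p = 0.000544, 0.00888, 0.00977 and 0.00888 for the secreted, stress, PPARA and cholesterol lists).

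In AhR-flox mouse hepatocytes Ahr (chromosome 12, 35497979 to 35534989), the targeted gene, stood at 10, 9.58 and 9.32 TPM with Ad-Cont and 7.14, 8.29 and 7.94 TPM with Ad-Cre in control samples. In B2-deprived samples it stood at 10.7, 10.1 and 9.89 TPM with Ad-Cont and 6.78, 6.99 and 7.52 TPM with Ad-Cre. The Ad-Cre difference in controls was −0.28 ± 0.09 (adjusted p = 0.494). The floxed exon is not given, and a tag at the transcript end checks nothing if it lies outside that exon. With Ad-Cont, deprivation raised the urate oxidase Uox by 2.45 ± 0.24 (66.9 ± 24.6 against 11.0 ± 1.67 TPM, adjusted p = 0.000126), the cardiac actin Actc1 by 2.36 ± 0.20 and the hypoxia-induced Ndufa4l2 by 2.28 ± 0.26. It lowered the chemokine Cxcl5 (−2.09 ± 0.16) and the kinase Cdk1 (−1.45 ± 0.12). The chemokine Cxcl2 fell to 8.62 ± 0.513 from 26.3 ± 0.171 TPM (adjusted p = 2.36e-06). Nqo1 fell by 0.93 ± 0.18, whereas Tiparp and Cyp1a2 did not pass (0.10 ± 0.13 and −0.07 ± 0.20). With Ad-Cre, deprivation raised Lipc, hepatic lipase, by 0.67 ± 0.09 and Ces1c by 0.65 ± 0.08, and lowered Wfdc2 (−0.46 ± 0.05). The interaction was 1.20 ± 0.16 for Cxcl2 (adjusted p = 0.00443) and 1.19 ± 0.16 for Cdk1 (0.00506).

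With Ad-Cont 525 genes were higher and 664 lower; the total of 1189 was 745 or 730 without control replicate 2 or 3 and 719 without deprived replicate 2. With Ad-Cre 26 were higher and 14 lower, a total of 40 (16 to 32 without 1 library). Voom gave 54 higher and 63 lower, limma without trend or robust settings 25 in total, no filter on low values 26, and only the groups of the contrast 134. Ad-Cre in control samples changed 3 genes, 2 higher and 1 lower (1 and 0 quantile-normalized), and 0 or 1 without any 1 library. Among those 3, Cenpa, a centromere histone, stood at −0.79 ± 0.11 (adjusted p = 0.039, and 0.0548 to 0.224 without any 1 library). The interaction held 22 above 0 and 8 below. Its total of 30 was 169 without Ad-Cont deprived replicate 1, 186 without Ad-Cre control replicate 3 and 11 to 47 without any other library. Of 8 macrophage markers 6 fell with Ad-Cont (7 adjusted by list), the complement chains C1qc and C1qa at −1.94 ± 0.16 and −1.92 ± 0.17, none passed with Ad-Cre (0 adjusted by list) and 3 differed upward (6 adjusted by list), C1qc by 1.68 ± 0.23. Those 3 were 5 without Ad-Cre control replicate 3, 3 without Ad-Cont deprived replicate 1 or 3 and 1 without any other 1 library, and 1 rose with Ad-Cont without deprived replicate 3. Of 14 acute phase genes 6 fell and 1 rose with Ad-Cont (7 and 2 adjusted by list), Cxcl1 at −1.07 ± 0.07, and 3 differed upward (5 adjusted by list; 7 without Ad-Cont deprived replicate 1). The 1 that rose was 0 without any 1 library but deprived replicate 3. Of 19 cell cycle genes 12 fell with Ad-Cont (15 adjusted by list), Birc5, a survival protein, at −1.53 ± 0.15, 3 fell with Ad-Cre (10 adjusted by list; 1 without its deprived replicate 2 and 0 without its control replicate 1 or 2 or deprived replicate 1 or 3), and 1 differed upward (7 adjusted by list; 2 without Ad-Cont deprived replicate 1 or 3 and 3 without Ad-Cre control replicate 3). Of 6 stellate cell markers 4 fell (5 adjusted by list; 2 without control replicate 3 or deprived replicate 2), Dcn, a collagen-binding proteoglycan, at −1.48 ± 0.16, and 1 with Ad-Cre (3 adjusted by list; 0 without any 1 library but its deprived replicate 3). Of 11 hypoxia genes 7 rose with Ad-Cont (8 adjusted by list), Bnip3 by 1.28 ± 0.18. With an estimated correlation the macrophage, acute phase and cell cycle lists held with Ad-Cont (adjusted p = 0.0115, 0.0115 and 0.0138), and the first pair held in the interaction (0.00837 each). The stellate and hypoxia calls with Ad-Cont were lost (adjusted p = 0.151 and 0.19 with an estimated correlation), as were the cell cycle in the interaction (adjusted p = 0.141) and the cell cycle and stellate calls with Ad-Cre (adjusted p = 0.111 and 0.174).

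In mouse liver, which carries the label of 4 weeks, 4 deprived columns were compared with 4 controls (n = 4 in this paragraph). Mup14, a major urinary protein gene (chromosome 4, 61300037 to 61303998), fell by 5.98 ± 0.65, from 1347 ± 631 to 23.8 ± 17.4 TPM (adjusted p = 0.00888). Slco1a4, an organic anion carrier, rose by 2.08 ± 0.32, from 26.2 ± 10.5 to 113 ± 39.4 TPM. Cyp4a14, a fatty acid hydroxylase and PPARA target, rose by 0.89 ± 0.13, and Ido2, of the kynurenine pathway, fell by 1.03 ± 0.17. Cyp2b9, a cytochrome P450, rose by 5.53 ± 0.74, a call lost without control column 3 (adjusted p = 0.0684). Fmo2, a flavin monooxygenase, rose by 1.99 ± 0.35, and Mup7 (−4.95 ± 0.81), Mup1 (−4.22 ± 0.60) and the serpin Serpina1e (−4.17 ± 0.68) fell. Without control column 1 these 4 had adjusted p of 0.089, 0.0953, 0.0711 and 0.0822, and without control column 3 they had 0.101, 0.102, 0.0779 and 0.102. Without control column 4, Fmo2, Mup7 and Serpina1e had 0.0619, 0.0596 and 0.0619. Without deprived column 3, Mup7, Mup1 and Serpina1e had 0.0804, 0.0571 and 0.0776, and without deprived column 2 Fmo2 had 0.0582. Mup copies share much of their sequence, so their single values are uncertain. Ahr, Cyp1a2, Nqo1 and Tiparp did not pass (0.73 ± 0.23, −0.50 ± 0.20, 0.64 ± 0.20 and 0.15 ± 0.17), Nqo1 having an adjusted p of 0.0463 without deprived column 4.

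In liver 221 genes were higher and 120 lower (78 and 143 quantile-normalized; all-gene median 0.142). The total of 341 was 66, 530, 68 or 171 without control column 1, 2, 3 or 4, and 131, 172 or 529 without deprived column 2, 3 or 4. Of 12 interferon-stimulated genes 1 fell (7 adjusted by list; 3 without control column 2 and 2 without deprived column 3). Isg15, a ubiquitin-like modifier, fell by 1.05 ± 0.22, a call lost without control column 1, 3 or 4 (adjusted p = 0.105, 0.114 and 0.0689) or deprived column 1, 2 or 4 (0.0526, 0.0735 and 0.0529). Of 15 PPARA targets 2 rose (6 adjusted by list; 1 without control column 1 or 3 and 4 without control column 2 or deprived column 1), Ehhadh, of peroxisomal beta-oxidation, by 1.11 ± 0.19, lost without control column 1 or 3 (adjusted p = 0.0594 and 0.0542). Of 15 kynurenine pathway genes 2 fell (4 adjusted by list; 1 without control column 1 or 3), Afmid, the formamidase, at −0.93 ± 0.16, lost without control column 1 or 3 (adjusted p = 0.0547 and 0.0542). Of 11 macrophage, 9 endothelial and 9 stellate cell markers none passed over all genes, and 0, 5 and 0 rose adjusted by list; 1 endothelial marker rose without control column 4. The interferon, PPARA and kynurenine lists passed (adjusted p = 1.8e-09, 0.0235 and 0.00186), but not with an estimated correlation (adjusted p = 0.611, 0.901 and 0.901).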

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

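The Kyn test and the 3 liver tests below were chosen after the results were seen, as were the thinning of reads as an alternative setting and the regrouping of what a model without the interaction leaves over; the other tests were fixed before their results were seen.

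Effects of deprivation differed between arms in 4 designs and those of Kyn in 1, each by the test of the difference itself. The interaction held 2676 genes with the AhR inhibitor, 6156 with the IDO/TDO inhibitor, 1712 with the AhR guide RNA and 30 with Ad-Cre, and for Kyn with the AhR inhibitor it held 1055. CYP1A1 had interactions of −2.99 with the AhR inhibitor, −1.31 with the IDO/TDO inhibitor and −2.83 with the AhR guide (limma, log2 scale). Cholesterol synthesis genes had a median of −1.29 relative to all genes in HepG2 and 0.263 in Caco-2, both at day 9, and this difference was not tested.

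With the IDO/TDO inhibitor the deprivation effect shrank from 7791 to 159 genes. Cells never deprived, through the medium or a label, would show none of the early response. The day 3 sets differed by 0.035, against 1.028 without inhibitor. The sets stood at 0.061 and 0.026 (limma fry adjusted p = 0.0799 and 0.797 over 6 tests, 0.0399 unadjusted for the higher). The day 12 higher set moved by 0.045 (adjusted p = 0.00132), which goes against this explanation. All genes had 0.027 there and other sets lost the call (0.021 in each), so it stays open. Kyn without deprivation did not give the whole response: it separated the day 12 sets by 0.126, where at least 1 was needed. Its dose is not given, and whether deprived cells need Kyn was not tested. Of the 159 genes, 84 moved as without inhibitor and 63 moved the opposite way, each past the test in both. An action of the inhibitor on the response, which the design names, stays open too and could not be separated from the first explanation.

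The AhR inhibitor interaction may come from the run, as libraries with inhibitor carry another date and folder in the headers. Whether these cells were also cultured apart is not given. If AhR were the source, its genes could be sought in the guide RNA interaction, where all libraries share a date. The higher minus the lower set lay there at −0.166. Of 614 genes called in both (384 for independent lists), 205 moved the same way, with Pearson −0.141 across 11599 genes. The guide alone changed 4365 genes in control medium, so this cannot decide. The run as the whole source stays open, as do untested actions of the inhibitor outside AhR. A depth difference is argued against by 2526 genes after thinning the reads to equal depth, and a single library that stands apart by 3244 genes without inhibitor control replicate 3. CYP1A1 moved the same way in both interactions (−2.99 and −2.83).

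In liver, genes known to differ between the sexes moved with the diet. Both sexes among the animals are argued against: the sum of 4 Y-linked genes lay between 56 and 85.9 TPM in all 8 libraries, and Xist at 0.054 TPM at most. Reads shared between Mup copies are argued against as the source of the male-biased fall, since 16 male-biased genes outside that family and Serpina1e had a median of −1.543 relative to all genes, 10 of them past the test (limma camera adjusted p = 3.06e-26, and adjusted p = 0.000605 with an estimated correlation). A shift of the sex-biased programme with the diet is a candidate explanation: 8 female-biased genes outside the highest fold changes had a median of 0.901, 6 past the test (camera adjusted p = 2.23e-07, and adjusted p = 0.00796 with an estimated correlation). These lists were written after the result was seen, and food intake, body weight and hormones were not tested.

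In the liver groups of 4 columns, the most distant value was tested for the named genes. Its gap to the nearest value took more of the group's range than Dixon's test allows in 4 of 30 groups of values, where chance gives about 1 in 20. These were Fmo2 (0.835) in controls, and Tiparp (0.904), Mup15 (0.971) and Mup17 (0.925) in deprived livers.

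Libraries were also regrouped at random within each comparison. In liver 1 of 35 splits, the real one, gave as many as 341 genes (highest other 0), so chance labels are excluded at that level. For the interactions, labels were permuted within each medium in 100 splits. As many genes as with the real labels came from 2 splits for the AhR inhibitor (2676 genes, highest other 5510), 4 for the IDO/TDO inhibitor (6156, highest other 6732), 3 for Kyn (1055, highest other 1122), 3 for Ad-Cre (30, highest other 96) and 8 for the AhR guide (1712, highest other 4199). The other splits as large (1, 3, 2, 2 and 7 in turn) all kept or turned the labels of 1 medium as a whole. They hold part of the real contrast and cannot measure chance. A test chosen after these counts were seen regrouped only what a model without the interaction leaves over, in 100 splits each. There only the real split gave as many genes for all 5 interactions, and the highest others gave 1, 1, 0, 2 and 5 in turn. A run difference would stay in those values too, so only chance labels are excluded.

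With 3 libraries against 3 there are 10 splits, and a share under 0.05 cannot be reached. The real and the highest other count were 592 and 1, 4120 and 0, 6134 and 1, and 6543 and 1 at days 3, 6, 9 and 12 in HepG2, and 4011 and 2 in Caco-2. They were 7331 and 1 without and 6857 and 0 with the AhR inhibitor, and 4278 and 1 for the inhibitor in control medium. They were 7791 and 0 without and 159 and 1 with the IDO/TDO inhibitor, and 1 and 2 for that inhibitor in control medium, where 3 splits gave as many. They were 7216 and 1 with the control guide, 6331 and 0 with the AhR guide, and 4365 and 2 for the guide in control medium. They were 1375 and 2 for Kyn, 1279 and 1 for Kyn with inhibitor, and 0 and 2 for the inhibitor in DMSO, where all 10 splits gave as many. In mouse hepatocytes they were 1189 and 1 with Ad-Cont, 40 and 2 with Ad-Cre, and 3 and 1 for Ad-Cre in controls.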

How the results depend on the processing

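Settings chosen after the data were seen are named above. Where a value moved, the cause was not tested. Scaling without the 10 highest genes left all 26 counts of called genes within 1.5 times, as did thinned reads for the 2 counts and the 4-library filter for the 1 count they were run on. Quantile normalization gave 748 genes in place of 1279 for Kyn with inhibitor (788 with median scaling), 1 in place of 3 for Ad-Cre in controls and 221 in place of 341 in liver. No filter on low values, which tests more genes, gave 53 in place of 159 with the IDO/TDO inhibitor, 0 in place of 1 for that inhibitor in control medium, 636 in place of 1055 for the Kyn interaction, 26 in place of 40 with Ad-Cre, 16 in place of 30 for its interaction and 131 in liver. Limma without trend or robust settings gave 84, 25 and 14 for the IDO/TDO inhibitor, Ad-Cre and the Ad-Cre interaction, where voom on recovered reads gave 319, 117 and 150. A pseudocount of 0.1 gave 0 and voom 7 for Ad-Cre in controls. With only the groups of the contrast there were 2693 in place of 4278 genes for the AhR inhibitor in control medium, 0 for the IDO/TDO inhibitor in control medium, 792 in place of 1189 with Ad-Cont, 134 with Ad-Cre and 7 for Ad-Cre in controls. Voom on recovered reads moved splits into higher and lower genes. The majority turned for deprivation without (2932 and 3020) and with the AhR inhibitor (3242 and 3403), without the IDO/TDO inhibitor (3478 and 3506) and in its interaction (2859 and 2571), with the control guide (3248 and 3370), with the AhR guide (3029 and 3181), for that guide in control medium (2207 and 2272) and in its interaction (1205 and 827), for Kyn with inhibitor (591 and 524) and in its interaction (711 and 450), with Ad-Cre (54 and 63), for Ad-Cre in controls (1 and 6) and in liver (95 and 186). It gave 164 and 155 with the IDO/TDO inhibitor and 87 and 63 for the Ad-Cre interaction. Scaling without the 10 highest genes gave 252 and 638 for Kyn with inhibitor, 289 and 568 for its interaction and 135 and 113 in liver. Depth limits low genes most: 1 TPM of a short transcript rests on few reads.

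Replicate numbers paired the libraries weakly at most. Those with the same number correlated at −0.108 to 0.187 over all tables (the IDO/TDO table holding both ends) and at −0.066 to 0.106 in the time course. By count 15 of 24, 0 of 6, 5 of 12, 5 of 12, 2 of 12, 4 of 12 and 2 of 12 libraries correlated best with their own number in the time course, Caco-2, AhR inhibitor, IDO/TDO inhibitor, guide RNA, Kyn and mouse hepatocyte tables, where chance gives about 1 in 3; the time course exceeded this, with correlations near 0. With the replicate number as a block, 2 genes in place of 1 were called for the IDO/TDO inhibitor in control medium and 0 in place of 3 for Ad-Cre in controls; 23 other counts stayed within 1.5 times, and 943 results for named genes stayed on their side of the threshold, 21 lost their call and 1 gained one. For lists 231 stayed and 2 gained a call, and all 34 results of the day 12 sets stayed. No paired analysis was possible for liver because its columns carry no number.

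Leaving out 1 library at a time gave 351 to 404 genes at HepG2 day 3, 60 to 166 with the IDO/TDO inhibitor, 0 to 1 for that inhibitor in control medium, 915 to 1137 for Kyn and 751 to 997 for Kyn with inhibitor. It gave 0 to 1 for the inhibitor in DMSO, 719 to 1081 with Ad-Cont, 16 to 32 with Ad-Cre, 0 to 1 for Ad-Cre in controls, 11 to 186 for its interaction and 66 to 530 in liver. In all, 139 such counts stayed within 1.5 times and 49 did not. For named genes 6501 such results stayed on their side of the threshold, 510 lost their call and 10 gained one.

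Of 989 results for named genes, 957 stayed on their side of the threshold under quantile normalization, 23 lost their call, 6 gained one and 3 turned: EPCAM at HepG2 day 9 (−0.037), and for Kyn with inhibitor FABP1 (0) and ALB (−0.379, from 0.47). Without trend or robust settings 940 stayed, 47 lost their call and 2 gained one. Of 244 results for lists, 75 lost their call with an estimated correlation and 169 stayed; under quantile normalization 4 lost it, 1 gained one and the secreted protein list turned in the Kyn interaction (camera adjusted p = 0.00412). The sets drawn from HepG2 day 12 changed sign under 2 other definitions. The higher set did so in Caco-2, as given above. The lower set did so for the AhR inhibitor in control medium when fixed at day 9 (−0.075), where it no longer passed. In the AhR inhibitor interaction the higher set lost its call at 0.58 (−0.073) and the lower set, at 0.035, gained one at 0.58 (0.086) and at day 9 (0.416), and ran from −0.04 to 0.107 without 1 library. With the IDO/TDO inhibitor the higher set lost its call at 0.58 and at day 9 (0.021 in each), as it did for Kyn at day 9 (0.035), and the lower set in the Kyn interaction at 0.58 (0.033).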

Other observations

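The culture-time test below was chosen after the values it rests on were seen; the gene lists were fixed before.

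Genes of flavin biology moved in both directions in the HepG2 time course at day 12. Of 13 acyl-CoA dehydrogenases and electron transfer flavoproteins, which hold FAD, 6 rose and 5 fell (as many adjusted by list; 3 fell without control replicate 2 or deprived replicate 1), and the list did not pass (limma camera adjusted p = 0.826). IVD, of leucine breakdown, rose by 0.67 ± 0.07 and ETFB by 0.65 ± 0.07, while ETFDH, which passes electrons to ubiquinone, fell by 0.63 ± 0.15. Of 41 other flavin enzymes 17 rose and 13 fell (18 and 14 adjusted by list; camera adjusted p = 0.927). FDXR, the reductase that supplies adrenodoxin, rose by 2.16 ± 0.13, SQOR, which oxidizes sulfide, by 1.59 ± 0.16 and TXNRD1, a thioredoxin reductase and NRF2 target, by 1.48 ± 0.06, and the flavin monooxygenase FMO5 fell by 2.25 ± 0.12. Of 6 genes of riboflavin transport and conversion 1 rose and 1 fell (as many adjusted by list, camera adjusted p = 0.768), the kinase RFK, which makes FMN, by 0.38 ± 0.08 and ENPP1 at −0.38 ± 0.07. In the AhR inhibitor, IDO/TDO and guide RNA sets, without inhibitor or AhR guide, 4, 5 and 4 rose and 1, 0 and 2 fell.

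Of 4 cholangiocyte markers 3 rose and 1 fell at day 12 (as many adjusted by list), and the list passed (camera adjusted p = 0.0126, and 0.0388 with an estimated correlation). SPP1 and the keratin KRT19 led it, KRT19 at 3.54 ± 0.07, with EPCAM at 0.33 ± 0.04 and SOX9 at −0.33 ± 0.05. SPP1 stood at 542 ± 13.8 TPM in day 3 controls as well.

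Control HepG2 cells changed over the days of culture more than deprived cells did in the genes that mark deprivation. ALB rose from 3063 ± 72.2 to 15930.0 ± 610 TPM between days 3 and 12 in controls, against 2725 ± 103 and 3188 ± 135 in deprived cells. HAMP went from 295 ± 23.6 to 0.92 ± 0.526 TPM in controls and from 259 ± 8.23 to 108 ± 12.4 in deprived cells. A candidate explanation is that the day 12 response partly reflects a smaller change with days in culture. It was tested on genes called in other libraries, those of the IDO/TDO set without inhibitor with a log2 fold change of at least 1. In time course controls the 860 higher genes had a median change from day 3 to day 12 of −0.71 (quartiles −1.22 to −0.30, 85.6% lower) and the 315 lower genes one of 1.02 (0.51 to 1.63, 10.5% lower), a difference of −1.732, where all genes had −0.21. In deprived cells the medians were 0.04 and −0.02, a difference of 0.06, where all genes had −0.12. The values are in line with that explanation, which may hold beside a direct effect of the vitamin; days and control cells were not varied apart from the medium, so growth, density or medium use by the controls stay open and untested.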
